A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

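Total RNA of *S. pombe* cells without dbr1, pooled from 41 conditions, was separated on 2-dimensional gels, and the circular fraction was sequenced in 2 libraries, 1 from a short and 1 from a long gel run. Per the submitters' processing notes, Bowtie 0.12.3 and SAMtools were used. The role of each tool, the peak caller, its thresholds, the annotation and the genome build are not given in the sources used here. Per the file headers, the authors deposited whole-number read counts per intron peak for annotated and added introns, read counts per circle with a skipped exon, and, for each intron, branch sequences with their distance to the 3′ splice site and read counts. The counts were not normalized, so they depend on intron length, gel recovery and library preparation together. Only the authors' names for the tables tie the annotated, added and branch tables to the short run. The lowest counts in the tables of annotated and added introns were 5 and 50, and how those limits arose is not stated.

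In the annotated table, 22 introns were listed a second time with identical values, and each was kept once, leaving 1292 of 1314 lines. Positions were read as 1-based and inclusive. They were compared with the NCBI ASM294v3 assembly and its annotation, in which 1259 of the 1292 introns matched an annotated intron exactly and all 1292 ran from GT to AG. Of the 222 added introns, 221 ran from GT to AG. All 817 introns of the branch table could be placed, in that the leading 7-nt sequence lay at the stated distance from the intron end. The share of annotated introns that were listed was computed over mRNA introns of up to 2000 nt in the reference annotation, which may differ from the authors' annotation. An intron counted as listed only where both ends equalled those of an intron in the authors' annotated table.

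Read counts were described by medians and quartiles, counts of single features by exact Poisson 95% intervals, and shares by Wilson or exact binomial 95% intervals. Relations across introns were given as Pearson's r on log10 values and Spearman's rho, and differences as differences of medians, each with a two-sided permutation test of 100000 resamples. The 8 p-values of this family were adjusted with the Benjamini-Hochberg method. The 8 gene lists were matched by gene name alone, in the file or in the reference annotation, so some members do not do what the list's name says, and each list's median was placed among 10000 random lists of the same size drawn from the table. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9. Simulated data had the sizes of the real tables, each with 400 draws and 999 permutations. The test of Spearman's rho across 1292 introns called 3.5% of draws with no relation, and 100% with an added slope of 1 chosen size. Pearson's r was not scored. These draws reshuffled the real read counts, so a low rate with no relation was built in, and dependence between introns of a gene was not simulated. The median test with 222 introns called 3.25% of draws with no shift and 91.75% with a shift of 0.4 on the log10 scale.

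The samples' groups, the tests, the gene lists, the alternatives and the rule for named genes were set before the data were examined, except where a choice is said to have been made later. The rule took the 10 highest and 5 lowest annotated introns and, in each gene list, the 2 highest and 1 lowest. It also took the 10 introns with most branch reads, the 5 with the lowest leading share among those with at least 20 branch reads, the 10 highest added introns and every skipped exon. Ties followed the order of the file. Alternatives changed the read minimum, the number of introns per gene, the division by length, the length range, the branch position and the way random lists were drawn. In matching on length, introns of equal length were taken in random order, because the file is ordered by reads.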

Results

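Lariat sequencing read the circular RNA of fission yeast (*Schizosaccharomyces pombe*) that lacks dbr1, the enzyme that opens the branched circle left when an intron is spliced out. Without it, excised introns stay as circles, so reads over an intron were taken to report its splicing. Other sources of such reads were not tested. RNA from 41 growth and treatment conditions was pooled. The circular arc was cut from 2-dimensional acrylamide gels in a short and a long run, with 1 library from each. The second dimension held 15% acrylamide in the short run and 20% in the long run. The tables of annotated introns, added introns and branch points carry the short run's name. The table of skipped exons covers both runs. Because the conditions were pooled, no condition was compared with another, and no value has a replicate. The peak tables held 9296300 reads over annotated introns and 895323 reads over added introns. These totals are sums over listed features and not library depths. All intervals cover counting error only and treat reads as independent. PCR copies are not independent molecules, so the intervals may be too narrow even for that error. Positions are as the files give them, and the genome build behind them is not given in the sources used here. All 1292 annotated introns listed began with GT and ended with AG at those positions in the ASM294v3 assembly.

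The first question was which annotated introns were recovered as circles, and at what level. Introns of ribosomal protein genes led the table, which held 1292 distinct introns of 1081 genes. Intron 1 of rpp102, which encodes an acidic ribosomal stalk protein, had 716954 reads (chromosome 2, 4009177 to 4009315, minus strand, 139 nt; 95% Poisson interval 715295 to 718616). The single introns listed for rpl31, rps13, rps2602 and rpp103 followed with 626617, 586655, 450739 and 314531 reads. The only introns among the 10 highest outside ribosomal protein genes were intron 1 of ero11, an oxidase of disulfide formation in the endoplasmic reticulum, with 305702 reads, and intron 5 of the snoRNA host transcript SPNCRNA.659 with 175833 reads. The other introns of that group were those of rps2801 with 289891 reads, rpl4301 with 237155 reads and rpl35b with 187743 reads. The 10 highest introns held 41.9% of all reads over annotated introns, and the 100 highest held 78.9%. The median intron had 438 reads (quartiles 52 and 2947), and the lowest value in the table was 5. That value was shared by 17 introns. The 5 named as lowest were the first of these in file order, namely intron 1 of mug8, of dad4 (a subunit of the kinetochore DASH complex), of srs2 (a DNA helicase) and of nep1, and intron 2 of rbx1. Those 5 introns measured 60, 59, 65, 80 and 63 nt.

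The gene lists fixed beforehand had medians from 112 to 3200.5 reads. The ribosomal protein list had 48 introns of 46 genes in the table, with a median of 3200.5 reads, and 29 of them lay above the table's median. Its median lay at percentile 100 of 10000 random lists of the same size, whose central 95% ran from 131 to 1362 reads. Name matching also took rpp1 and rpp40, which encode RNase P subunits, and without them the median was 3200.5 reads (percentile 99.99). The list held 42.2% of all reads over annotated introns. Its 30 introns of 80 to 200 nt had a median of 22056.5 reads, and its 18 introns outside that range had a median of 41 reads. The lowest count in the list, 11 reads, was shared by intron 1 of rpl702 (291 nt), of rps502 (288 nt) and of rpl8 (66 nt). The list of meiosis and mating genes lay at the other end. Its 40 introns of 33 genes had a median of 112 reads, at percentile 1.74, against 121 to 1465 reads for the central 95% of random lists. Members of that list still reached high values, with 38475 reads for intron 1 and 25884 reads for intron 3 of mug64, while intron 1 of mug8 had 5 reads. Of its genes, 5 were taken only by an older mug name, namely those now called dph6, epr1, snx41, teb1 and atg1802. Without them the median was 92 reads (percentile 1.21), and without all genes taken by a mug name it was 64 reads over 17 introns (percentile 2.44). Resampling the members gave 95% ranges of percentile 13.4 to 100 for the ribosomal protein list and 0 to 39.4 for the meiosis and mating list.

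The other 6 lists had medians inside the central 95% of their random lists. The 40 introns of the ubiquitin and proteasome list had a median of 582 reads (percentile 67.3). Intron 2 of pre6 and intron 2 of pup2, both genes of 20S proteasome subunits, had 25070 and 24885 reads, and intron 2 of rbx1, which encodes a RING subunit of cullin ligases, had 5 reads. The 23 introns of the transcription list had a median of 604 reads (percentile 66.1). Intron 5 of rpb1, the largest subunit of RNA polymerase II, had 29426 reads, intron 1 of rpa43, a subunit of RNA polymerase I, had 24307 reads, and intron 2 of rpb5 had 8 reads. The 52 introns of the small GTPase and vesicle list had a median of 272 reads (percentile 17.9). Intron 1 of cdc42, a polarity GTPase, had 75920 reads, intron 4 of the Rab GTPase gene ypt1 had 43414 reads, and intron 3 of sec231, a COPII coat gene, had 5 reads. The 25 introns of the splicing list had a median of 266 reads (percentile 25.3). Intron 1 of rsd1 had 13582 reads, intron 4 of lsm3, a subunit of the Lsm ring, had 10413 reads, and intron 6 of usp105, a U1 snRNP gene, had 8 reads. The 18 introns of the cytoskeleton list had a median of 231.5 reads (percentile 22.2). Intron 3 of arp3 and intron 3 of arc5, both genes of the Arp2/3 complex, had 12025 and 10401 reads, and intron 1 of tbc1 had 8 reads. The 39 introns of the respiratory chain and mitochondria list had a median of 364 reads (percentile 38.1). Intron 1 of cyt1, encoding cytochrome c1, had 13001 reads, intron 1 of sdh1, a succinate dehydrogenase gene, had 9045 reads, and intron 1 of tom20 had 6 reads. The percentiles describe 1 library and carry no test.

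Recovery followed intron length. Of the 1117 mRNA introns of 80 to 200 nt in the reference annotation, 1000 were listed, which is 89.5% (Wilson 95% interval 87.6 to 91.2). Of the 2968 introns under 60 nt, 4 were listed, which is 0.135% (0.0524 to 0.346). Of the 339 introns of 201 to 2000 nt, 156 were listed, which is 46.0% (40.8 to 51.3). No intron of up to 50 nt was listed among 2034. The median read count rose from 148 at 80 to 89 nt to 3602 at 160 to 179 nt, was 1018 at 180 to 200 nt, and was 45 at 201 to 250 nt. Introns of 80 to 200 nt held 99.5% of all reads over annotated introns. Across all 1292 introns, read count and length gave Spearman's rho of 0.160 (permutation p = 1e-05, adjusted p = 1.6e-05) and Pearson's r of 0.0182 on log10 values (permutation p = 0.51, adjusted p = 0.51). Within 80 to 200 nt, a range chosen after the data were seen, rho was 0.362 and r was 0.348 (n = 1027, permutation p = 1e-05 for each). Over 200 nt both were negative, at -0.305 and -0.249 (n = 160, permutation p = 0.00016 and 0.0018). With reads divided by length, rho was 0.0217 (permutation p = 0.43). Introns are not independent replicates. All permutation tests were two-sided, 1e-05 is the smallest p they can give, and 8 relations or differences were adjusted together with the Benjamini-Hochberg method.

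**Figure D1:**
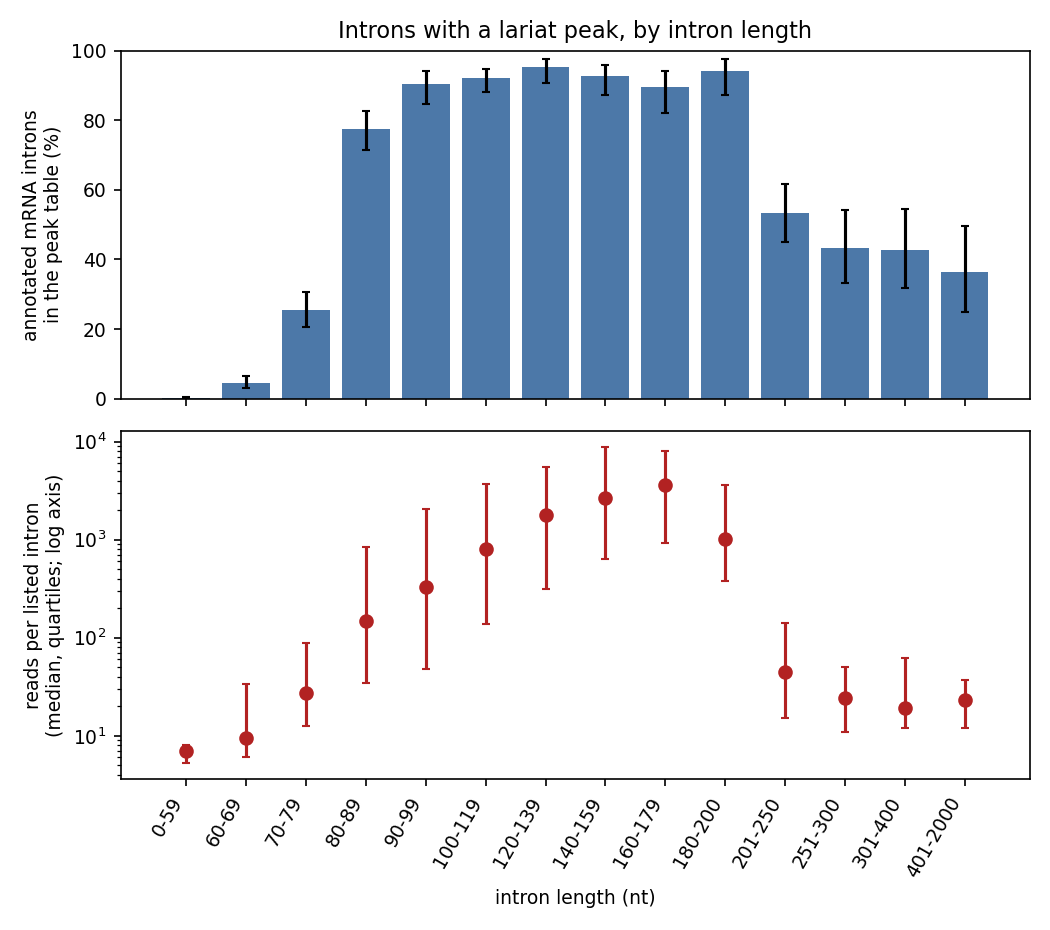
The upper panel plots the percentage of annotated mRNA introns in each length range (nt) that were listed, with Wilson 95% intervals, and the lower panel plots the median reads per listed intron with quartiles on a log axis. Listing stood at 77.5% for 80 to 89 nt and at 25.3% for 70 to 79 nt, and the median read count was highest, at 3602, for 160 to 179 nt.

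The position of an intron in its gene was compared next. In 181 genes with 2 or more listed introns, the first listed intron had a higher count than every later listed intron in 84 genes, which is 46.4% (exact binomial 95% interval 39.0 to 54.0). Drawing a listed intron of each gene at random would give 47.3%, inside that interval. Within 80 to 200 nt, the first was higher in 60 of 136 genes, which is 44.1% (35.6 to 52.9).

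Reads that crossed the branch located the branch point in 817 introns. These had 21802 branch reads at 1011 positions, with a median of 4 reads per intron (quartiles 2 and 15). Intron 1 of rps2402 (SPBC17G9.07), a ribosomal protein gene, had the most, with 1822 branch reads, of which 98.6% lay at AGCTAAC, at a distance of 12 nt from the 3′ splice site as the file counts it. Intron 1 of rpl31 followed with 1302 branch reads at a leading TACTAAC, and intron 1 of asn1, an asparagine synthetase gene, with 1230 at a leading TAGTAAC. The other introns with most branch reads were intron 1 of rps13 with 849, of rpl3801 with 483, of SPBC24C6.04 with 452, of rho2 with 380, of rps1201 with 371 and of rpp102 with 336, and intron 3 of amk2 with 323. The leading position held 98.0% of branch reads over all introns (Wilson 95% interval 97.8 to 98.2). That interval counts reads as independent, although they are grouped by intron. In 650 introns a single position was listed, but 190 of these had only 1 branch read and could show no other position. Among the 175 introns with at least 20 branch reads, intron 3 of apm1, encoding a clathrin adaptor subunit, had the lowest leading share. There, 23 of 31 reads lay at TATTAAT and 8 at TTCTAAT, giving 74.2% (56.8 to 86.3). The listed distances of these 2 sequences were 10 and 16 nt. Intron 2 of SPBC15C4.02 had 29 of 36 reads at its leading position (80.6%, 65.0 to 90.2), with the other 7 at AACTGAC. Intron 2 of eme1, a nuclease subunit gene, had 24 of 28 (85.7%), intron 3 of SPAC1B3.02c had 60 of 70 (85.7%), and intron 2 of ssb3 had 19 of 22 (86.4%).

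The leading sequences shared a short pattern. Position 6 of the 7-nt sequence, taken here as the branch base, was A in 817 of 817 introns (Wilson 95% interval 99.5 to 100%). It was also A at all 1011 positions listed, so a search limited to A by the authors cannot be excluded from the file. Position 4 was T in 808 introns (98.9%), position 5 was A in 752 (92.0%), position 3 was C in 671 (82.1%) and position 7 was C in 599 (73.3%). The most frequent sequence was TACTAAC, in 136 introns (16.6%, 14.2 to 19.4), followed by TACTAAT in 71, TGCTAAC in 67, TTCTAAC in 56 and TATTAAC in 55. There were 87 different leading sequences. The listed distance to the 3′ splice site had a median of 11 nt (quartiles 9 and 13, range 5 to 277), and 795 introns lay within 20 nt. That distance counts the bases between the end of the 7-nt sequence and the end of the intron. The base at position 6 therefore lies further from the splice site than the distance given. Distance rose with intron length, with rho of 0.151 (permutation p = 2e-05, adjusted p = 2.3e-05) and r of 0.365 on log10 values (permutation p = 1e-05, adjusted p = 1.6e-05, n = 817). In the 175 introns with at least 20 branch reads, r was 0.201 (permutation p = 0.0073). A distance cannot exceed the length of its intron, and 14 introns had a listed distance over 40 nt. How much this bound and these introns added to the relation was not tested.

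**Figure D2:**
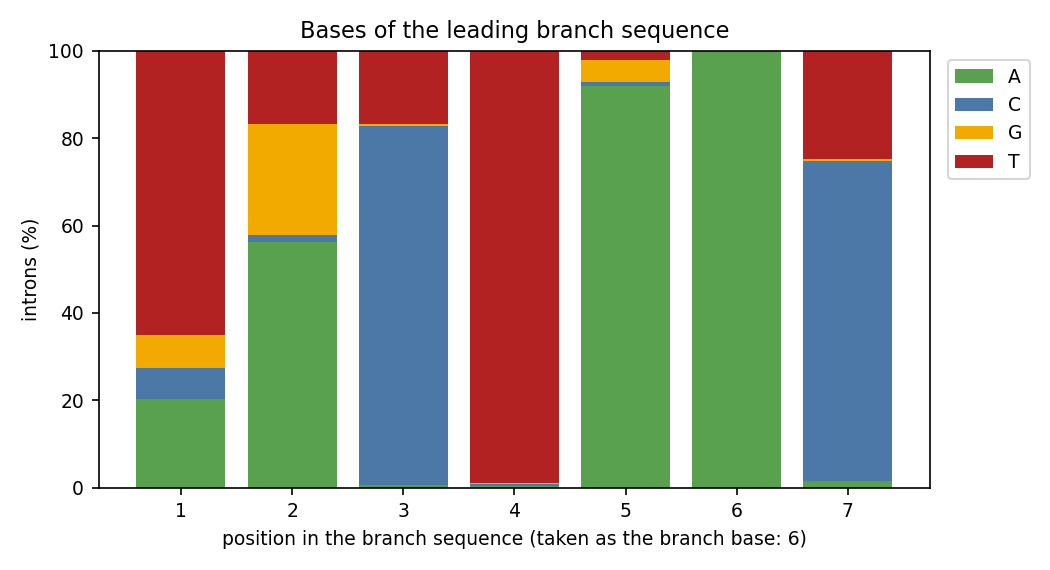
Stacked bars give the percentage of 817 introns with each base at each of the 7 positions of the leading branch sequence. Position 6 was A in every intron, and position 4 was T in 98.9%.

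Branch reads were compared with peak reads in the 760 introns found in both tables. Across these introns, Spearman's rho was 0.452 and Pearson's r was 0.471 on log10 values (permutation p = 1e-05 and adjusted p = 1.6e-05 for each), and introns are not independent replicates. The median of these introns had 4.69 branch reads per 1000 peak reads (quartiles 1.16 and 19.3), and the pooled value was 2.52. A further 532 of the 1292 annotated introns listed had no branch reads and were left out. The correlation and the ratio therefore describe only introns with branch reads. Intron 1 of rpp102 combined 716954 peak reads with 336 branch reads, whereas intron 1 of rho2 combined 933 peak reads with 380 branch reads.

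The authors also listed 222 introns outside their annotation, called added introns here. Introns tied to snoRNAs had the highest counts. The intron at SPNCRNA.445 (chromosome 2, 3874462 to 3874797, minus strand, 336 nt) had 364089 reads, whereas listed annotated introns of 301 to 400 nt had a median of 19. The intronic snoRNAs SPSNORNA.01 and SPSNORNA.19 had 119242 and 104507 reads, and introns in 3′ untranslated regions that hold a snoRNA had 59282 reads at spt20 and 50379 reads at SPSNORNA.30. The 9 introns of snoRNA classes held 78.3% of reads over added introns. Whether these reads came from the intron circle or from the snoRNA was not tested. The remaining introns among the 10 highest were antisense to SPCC550.12 with 49228 reads and to rds1 with 47060 reads, in the 5′ untranslated region of SPBC1289.13c with 13138 reads, in the non-coding RNA SPNCRNA.477 with 9336 reads, and in the 3′ untranslated region of SPAC1639.01c with 8197 reads. By class, 58 were antisense, 45 lay in 5′ untranslated regions, 39 in 3′ untranslated regions, 25 in coding sequence and 22 in non-coding RNA. Of the 25 in coding sequence, the authors classed 19 as frameshifting and 6 as in-frame.

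The added introns had fewer reads than annotated ones, with a median of 117 against 438. The difference in median log10 reads, added minus annotated, was -0.573 (permutation p = 1e-05, adjusted p = 1.6e-05). The added table started at 50 reads and the annotated table at 5. With both sets at 50 reads or more, a limit chosen after the data were seen, the medians were 117 and 1183 and the difference was -1.005 (permutation p = 1e-05). Against annotated introns matched on length it was -1.08 (permutation p = 1e-05). Added introns were longer, with a median of 139 nt against 118 nt, a difference of 21 nt (permutation p = 2e-05, adjusted p = 2.3e-05). With both sets at 50 reads or more, the medians were 139 and 123 nt and the difference was 16 nt (permutation p = 0.00018). In mean log10 length, over all introns of both sets, the difference was 0.0251 (permutation p = 0.044).

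**Figure D3:**
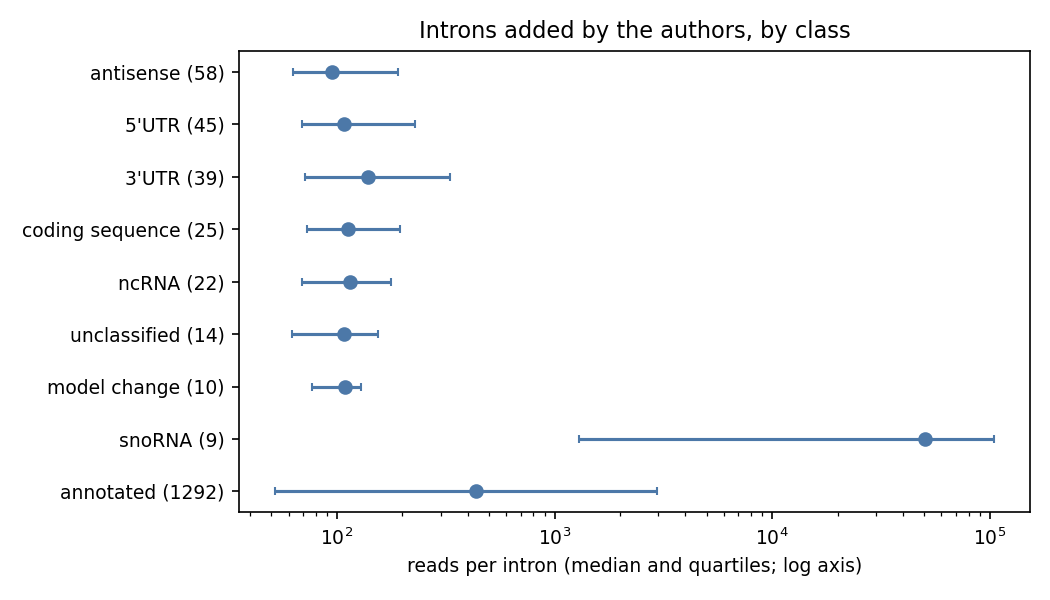
Points are the median reads per intron on a log axis and bars the quartiles, for each class of added intron and for annotated introns, with the number of introns in brackets. The snoRNA classes had a median of 50379 reads, and the antisense class had 94.5.

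Circles that hold a skipped exon were listed for 23 events in 22 genes, and each listed length equalled the exon plus both flanking introns in the reference annotation. Exon 2 of nup107, a nuclear pore gene, had 851 reads (circle on chromosome 2, 441752 to 441915, minus strand, 164 nt; 95% Poisson interval 795 to 910). Exon 3 of alp41, an Arf-like GTPase gene needed for tubulin folding, had 663 reads, and exon 5 of the same gene had 309. The runs that listed an event are named in the file, but its count is not divided between them, and no test between the gels was possible with 1 library each. The other events listed in both runs were exon 2 of qcr10 (respiratory complex III) with 314 reads, exon 2 of vrs1 (valyl-tRNA synthetase) with 311, exon 3 of hus1 (a checkpoint clamp subunit) with 107, exon 3 of pth1 with 83, exon 3 of duf757 with 76 and exon 2 of pre3 (a 20S proteasome subunit) with 73. The 5 events of the short run alone were exon 2 of sr140 with 349 reads, exon 3 of ubc15 (a ubiquitin-conjugating enzyme) with 158, exon 3 of ats1 with 139, exon 2 of SPCC126.11c with 73 and exon 2 of pca1 (metacaspase) with 63. The 9 events of the long run alone were led by exon 2 of lat1, a subunit gene of pyruvate dehydrogenase, with 307 reads. The others were exon 6 of mettl16 with 154, exon 2 of aim27 with 120, exon 2 of nep1 with 94, exon 2 of srrm1 with 89, exon 4 of lig4 (a DNA ligase) with 85, exon 2 of trm402 with 78, exon 2 of rpn1301 with 63 and exon 2 of rho2 with 61. Circles listed by the long run alone measured 188 to 279 nt. The other 14 measured 121 to 184 nt.

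**Figure D4:**
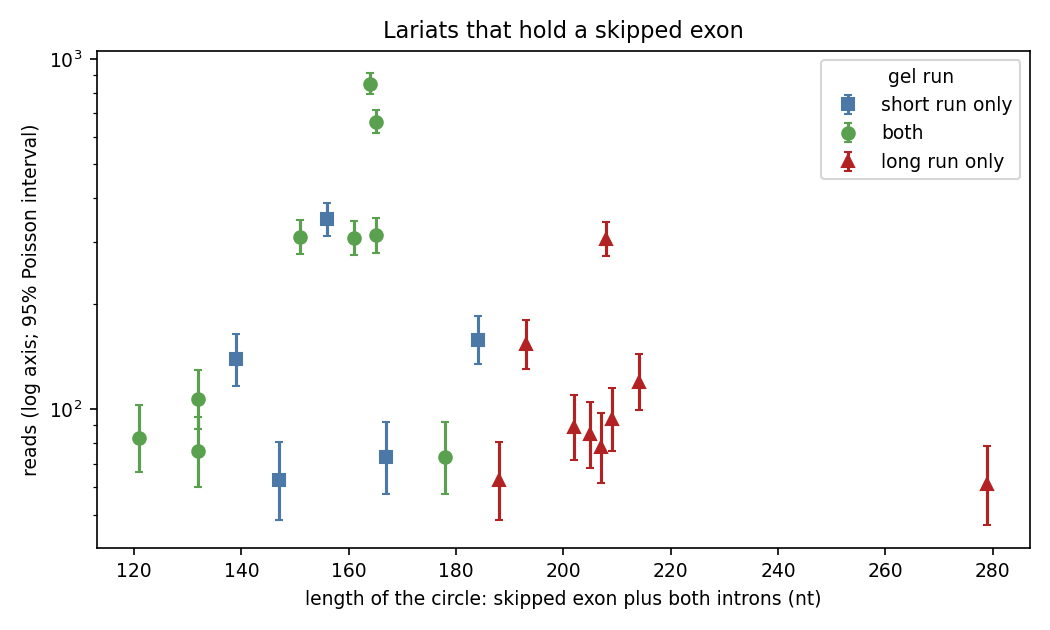
Each point is a skipped exon, with the length of the circle in nt on the x axis and reads with a 95% Poisson interval on a log y axis, marked by the gel run that listed it. The 9 events of the long run alone lie between 188 and 279 nt, above the 14 others.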

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

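Each result was recomputed under its alternatives, 91 values in all. Of these, 35 were percentiles of gene lists, whose limits were too wide to decide anything. Of the other 56, 45 stayed the same, which meant counts within 1.5 times, shares and medians within their 95% interval, and tests with the same direction and side of the 0.05 threshold. Some of these could not have changed. Every listed branch position has A, a minimum of 10 reads removes no skipped exon since the lowest had 61, and all 817 leading sequences were placed. The alternatives restricted to 80 to 200 nt, to over 200 nt or to 50 or more reads were chosen after the data were seen. So were those without snoRNA classes, those that left out members of a gene list and the check on placed branch sequences. The relation of reads to intron length depended most on the setting. Pearson's r, 0.0182 over all introns, was -0.0149 at 10 or more reads (permutation p = 0.6) and -0.146 with reads divided by length. It was 0.260 without the shortest and longest 10%, 0.348 for 80 to 200 nt and -0.249 over 200 nt. Spearman's rho was 0.0217 with reads divided by length and -0.305 over 200 nt. The opposite signs inside and above 200 nt show that no single slope describes the table. The number of introns with branch reads was 407 at 5 or more reads and 175 at 20 or more, where the leading share was 98.2%, by construction of those minimums for the counts. The short run, alone or together with the long run, listed 14 of the 23 skipped exons. Percentiles of gene lists moved, for small GTPases from 17.9 to 52.2 and for the cytoskeleton from 22.2 to 7.89 with introns of 80 to 200 nt, and for transcription from 66.1 to 92.3 with 1 intron per gene. These lay inside the 95% ranges from resampling members, 0.24 to 95.4, 4.49 to 99.95 and 9.64 to 99.93, which are too wide to show stability. The difference between added and annotated introns was -0.358 with means in place of medians. No paired analysis was possible because each gel run has 1 library. Counts near the minimum of 5 reads limit what can be said of introns under 60 nt and over 200 nt.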

Other observations

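The test of reading frame was chosen after the exon lengths were seen, as was the comparison with circle length held. The introns in this paragraph were also chosen after their values were seen. In the annotated table, the transcript SPNCRNA.659 (snoZ), whose intron 5 was named above, had 4 listed introns, with 175833, 137088, 83031 and 422 reads, of which the lowest was also the longest at 206 nt. Together they held 4.26% of all reads over annotated introns. Whether their reads came from the intron circles or from a snoRNA was not tested, nor was length as a source of the lowest count. Intron 1 of SPNCRNA.1038, which the reference annotation lists as the snoRNA snR90, had 7801 reads, and intron 1 of SPNCRNA.1508 had 3006 reads. Of the 58 antisense introns, 41 lay inside a protein-coding gene on the opposite strand and 33 inside a long non-coding RNA on their own strand in the reference annotation.

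The frequencies of splice signals are given as values only, because the authors' calling rules are not known. A 5′ end of GTANGT was found in 69.8% of annotated introns (Wilson 95% interval 67.3 to 72.3). Among added introns it was found in 66.7% of the snoRNA classes (35.4 to 87.9), 62.2% of the 5′ untranslated region class (47.6 to 74.9), 56.9% of the antisense class (44.1 to 68.8), 45.5% of the non-coding RNA class (26.9 to 65.3) and 42.9% of the unclassified (21.4 to 67.4). It was found in 36.0% of the coding sequence class (20.2 to 55.5), 33.3% of the 3′ untranslated region class (20.6 to 49.0) and 20.0% of the model changes (5.67 to 51.0). A CTRAY sequence within the last 40 nt was found in 81.6% of annotated introns (79.4 to 83.6), in 90% of model changes (59.6 to 98.2) and in 88.9% of the snoRNA classes (56.5 to 98.0). The shares were 78.6% of the unclassified (52.4 to 92.4), 76.0% of the coding sequence class (56.6 to 88.5), 74.4% of the 3′ untranslated region class (58.9 to 85.4), 64.4% of the 5′ untranslated region class (49.8 to 76.8), 54.5% of the non-coding RNA class (34.7 to 73.1) and 53.4% of the antisense class (40.8 to 65.7).

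Of the 1117 mRNA introns of 80 to 200 nt in the reference annotation, 117 had no exact match in the authors' annotated table, and 48 of these measured 80 to 89 nt. They include 4 that overlapped a listed intron. Among these, intron 4 of spt20 and intron 6 of crd1 (SPAC22A12.08c) were in the table of added introns, with 59282 and 5928 reads, and intron 1 of asn1 was listed with another end. All 3 introns of rec6, a meiotic recombination gene, that lay in this range were unlisted, as were 6 of the 15 introns of wtf genes. Branch reads were nevertheless found for intron 2 of ncs1 (46 reads, 118 nt) and intron 2 of brf1, a gene of the RNA polymerase III factor TFIIIB (34 reads, 157 nt), neither of which had a listed peak. In all, 57 introns with branch reads had no peak, of which 39 were under 80 nt. Of the 57, 36 had only 1 branch read and 4 had 10 or more. Secondary branch positions lay 1 nt upstream of the leading position in 117 of 194 cases and 1 nt downstream in 3. Whether this reflects a shift of the read end could not be tested, because every listed position has A as its branch base.

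Low read counts outside 80 to 200 nt may come from the genes that carry such introns or from the size range of the gel and library steps. In genes with an 80 to 200 nt intron at or above the median read count of such introns, 0 of 398 introns under 60 nt were listed (0%, Wilson 95% upper limit 0.956%), and in genes with any listed 80 to 200 nt intron it was 2 of 812 (0.246%). A further check was chosen after these values were seen. In genes that carry an intron under 60 nt, 483 of 540 introns of 80 to 200 nt were listed (89.4%, 86.6 to 91.8), against 517 of 577 in other genes (89.6%, 86.8 to 91.8). The median read counts of the listed ones were 760 and 1158, a difference that was not tested. Because 1000 of all 1117 introns of 80 to 200 nt were listed, the share of 483 among 540 had to be high. It is therefore no separate test of low expression for introns under 60 nt. It shows only that 80 to 200 nt introns were listed at near-equal shares in genes with and without an intron under 60 nt. This covers only genes that also have an 80 to 200 nt intron. Expression of the other genes could not be judged in this way. Only 4 of the 2968 reference mRNA introns under 60 nt were listed, so the shares among 398 and among 812 had to be low. Their near-absence in these genes therefore gives a size range no support of its own. In 60 genes with introns in both ranges, the intron over 200 nt had the higher count in 3 (5%, 1.71 to 13.7). For the introns over 200 nt of these genes, this argues against low expression as the whole cause. Introns over 200 nt of other genes were not covered. The lower count in the other 57 (95%, 86.3 to 98.3) is the same comparison and gives a size range no support of its own. A size range, and the gel, library and peak-calling steps as its source, stay open. For introns under 60 nt, low expression of the genes that carry them was not decided either.

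Antisense introns could in principle be annotated introns assigned to the wrong strand. Of the 58, 0 overlapped an annotated intron on the opposite strand (0%, Wilson 95% upper limit 6.21%). None of those listed was therefore a reference intron placed on the wrong strand. The authors listed introns outside their annotation by rules not known here, so this outcome may have been fixed by the calling. It gives no measure of strand errors in the reads. Other sources of such introns were not tested.

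The skipped exons were examined for reading frame and length. Of 23 skipped exons, 6 (26.1%, Wilson 95% interval 12.5 to 46.5) had a length that was a multiple of 3, against 36.4% of 1209 coding internal exons whose skipping would give a circle of 121 to 279 nt, so selection for frame-keeping exons was not detectable with 23 events. Their median length was 65 nt against 89 nt for the 1186 such exons that were not listed, a difference of -24 nt (permutation p = 0.028). Their circles were also shorter, with a median of 167 nt against 204 nt, and with circle length held the difference was -7 nt (permutation p = 0.22). Short exons and short circles therefore cannot be told apart as the source of the difference with these counts.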
